A study of Rattus norvegicus with 6 samples.

How the data were processed

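RNA of 6 rat lung samples, 3 control and 3 banding, was measured on Affymetrix rat expression arrays. The extraction fell 9 weeks after the operation, and 3 ug of total RNA per array was labelled with biotin, per the labels' protocols. The values used here are log2 signals per probe set that the authors deposited as a table of 6 columns. They were made with GCRMA, per the submitters' processing notes, a method that corrects the background by probe sequence, normalises the arrays by quantiles and summarises the probes of a set; its version and settings are not given in the sources used here. The log2 scale was read from the values, all of which lie between 0.46 and 14.2 with array medians of 3.30 to 3.35, and no sign of centring per gene was seen. The arrays' scan dates and scanner files were not used here, so batches could not be tested.

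Groups and replicate numbers were taken from the sample titles. The table holds 31099 probe sets, of which 57 Affymetrix control probe sets were left out. Probe sets were named through the platform annotation, which is older than the present gene catalogue, and symbols were updated by gene number through a table of the rat assembly GRCr8, used for names only and not for coordinates. Of the probe sets, 20826 had 1 symbol, 436 had several and 9780 had none, and 68 of those with 1 symbol were absent from the newer table and kept the older name. Only probe sets with 1 symbol were named. A gene was represented by its probe set with the highest mean over all 6 arrays.

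A probe set was tested if its log2 value reached 4 on at least 3 of the 6 arrays, a filter blind to group, which left 13935 probe sets and 8841 genes. Banding was compared with control with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are those of limma's moderated fit, and SDs are those of the group's arrays. The median log2 difference over all probe sets tested was 0.02. Array 3' and 5' signals of beta-actin, a sign of RNA integrity, differed by 2.07 to 2.52 log2 units in controls and 1.83 to 2.24 in banding lungs.

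The 31 gene lists (cell type markers, pathways and check lists for blood, fat, muscle and sex) were fixed before the data were examined, as were the main test and the rule for named genes. Of them 26 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, which compares a list with all other genes. All 7 lists that passed lost the call when camera estimated the correlation between genes, where 0 lists passed. With fry, which asks whether a list's genes move on balance in a single direction, 10 lists passed, and 21 passed fry's test for changes in either direction. Named genes were the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap (placeholder symbols skipped), up to 4 members of each list with the smallest p, every measured mast cell gene, and 5 genes given whatever their values (Bmpr2, Edn1, Nppa, Nppb and Acta2). Genes named outside this rule are said to have been chosen after their values were seen. Where a group mean of a named gene that passed lies below 4, its fold is given with values below 4 raised to 4, as "at least".

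The test was tried on simulated data with the means and spreads of the real 13935 probe sets, in 5 runs with 200 changed probe sets each. It called 8.8% of probe sets changed by 0.5 log2 units, 51.6% at 1, 87.2% at 2 and 96.8% at 3, and 4.53% of all its calls were false. The real data gave 1034 calls, so the adjustment was stricter in the simulation and these shares do not carry over to the real comparison. In 20 simulated runs over the 8841 genes, camera called a list shifted by -0.6 in 20 of 20 and 4 of 500 other list tests; these simulations hold no correlation between genes. The alternatives were other level filters, quantile normalisation, median centring, no variance trend, a robust fit, array weights, a replicate block, the mean of a gene's probe sets, other list tests and leaving out each array. Further alternatives were chosen after seeing the data: leaving out control 3 and banding 1 together, averaging banding 2 and banding 3, raising low values to 4, and counting the changed members of each list and the changed MHC probe sets without each array.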

Results

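Gene expression was measured in rat lung after aortic banding, an operation that narrows the aorta, loads the left ventricle and, through heart failure, raises pressure in the lung circulation. The series holds 6 lung samples: 3 from control rats and 3 from banded rats, which the labels describe as having pulmonary hypertension from heart failure. RNA was taken 9 weeks after the operation, and each sample was hybridised to its own Affymetrix rat expression array. The labels do not say that each array stands for a separate animal, so p-values measure the spread between these samples, which may be technical. The labels used here give no strain, so a difference in stock between the groups could not be told apart from banding. Precision is limited by the number of arrays, 3 per group. The deposited values had near-equal distributions, with array medians of 3.30 to 3.35 on the log2 scale.

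The comparison of banding with control lungs asks which transcripts differ in lungs with pulmonary hypertension that follows left heart failure. Macrophage genes were higher in the banding lungs: Trem2, a lipid-sensing receptor of macrophages, rose from 2.47 ± 0.57 to 6.54 ± 0.14 (log2 mean ± SD, n = 3 each; at least 5.82-fold with values below 4 raised to 4), and Mrc1, the mannose receptor, rose from 9.78 ± 0.13 to 11.4 ± 0.28. Of the endothelial genes measured, 9 of 26 fell, and of the genes of alveolar type I cells, the flat cells of the gas-exchange surface, 5 of 12 fell, with Cav1 counted in both. With an array left out these counts ran from 2 (without control 1) to 14 (without banding 1) and from 0 (without control 1 or banding 3) to 5. The largest of these falls was that of Car4, a membrane-bound carbonic anhydrase of lung capillaries, which was 7.49-fold lower. Of the mast cell genes 6 of 11 rose, among them the chymase Cma1, and 1 fell. The list did not pass the list test (camera adjusted p = 0.068), and 2 (without control 1 or control 3) to 7 (without control 2) rose with an array left out. Of T and NK cell genes 3 of 8 fell, among them the chemokine Ccl5, which was 5.59-fold lower. Of this list 4 fell without control 3 but 1 without any other single array. Hmox1, the enzyme that breaks down heme, was 6.98-fold higher.

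**Figure D1:**
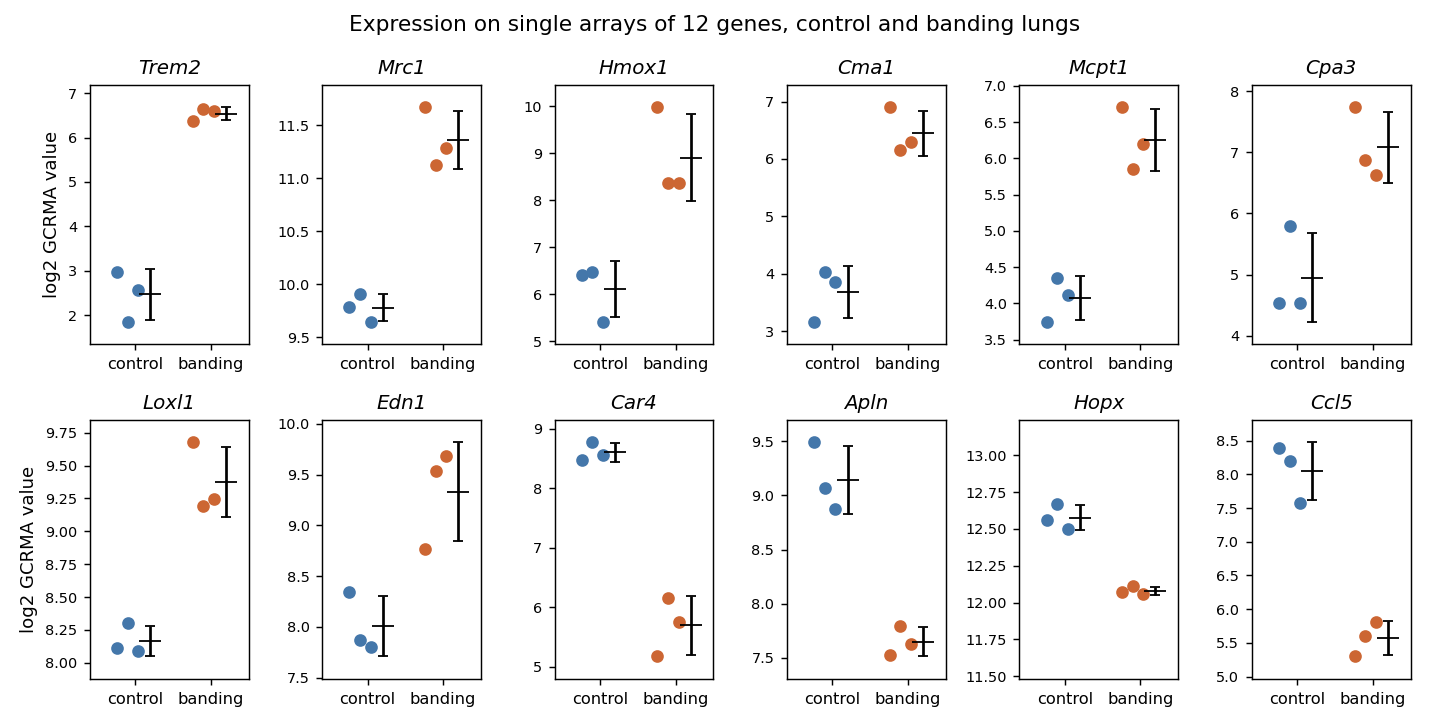
Log2 GCRMA values of 12 genes on the 3 control arrays (blue points) and the 3 banding arrays (orange points), each panel with its own vertical axis. Black bars give the group mean and SD. The groups do not overlap in any of these genes, which holds for all 719 genes that changed. Car4 lies at 8.60 in controls against 5.70 in banding lungs.

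Of 13935 probe sets tested with limma, 1034 changed at an adjusted p below 0.05, 638 higher and 396 lower in banding lungs, and 501 of them changed at least 2-fold (323 higher and 178 lower). Counted by gene, 719 of 8841 changed, with 487 higher and 232 lower. The 3 control and 3 banding values did not overlap in 35.2% of the genes tested, where 10% is the average over random groupings. Genes vary together, so the share in a single grouping can lie far from that average. Whether 35.2% exceeds chance was not tested. A permutation of single genes cannot go below an exact p of 0.1 in this design. Banding 1 lay farthest from the controls: its correlations with the 3 controls were 0.913 to 0.919, against 0.952 to 0.962 for banding 2 and banding 3, and the latter pair was the most alike of all arrays (r = 0.992 across probe sets, which are not independent replicates). The number of changed probe sets depended on single arrays: it was 344 without control 1, 498 without control 2, 375 without control 3, 551 without banding 2 and 359 without banding 3, but 1240 without banding 1. Of the 87 genes named by the fixed rule that passed, 37 passed in each of the 6 fits that left out an array and 55 in at least 3 of them; the 37 were C6, Frzb, Trem2, Fst, RT1-CE10, Cemip, Serpine2, Cxcr1, RT1-T24-3, Vtn, Pdia5, Kcnk2, RT1-N2, Car4, Cma1, Mcpt1, Myl9, Loxl1, Ltbp2, Ctss, Mmp14, Apln, Ccl21, Stab1, Mmrn1, Chi3l1, Mrc1, Gpnmb, Ccl5, Hp, Slc40a1, Tbxas1, Sgk1, Il18, Kitlg, Bhlhe41 and Ndrg1.

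Among the largest rises, C6, a terminal complement component, was at least 9.63-fold higher, and Frzb, a secreted Wnt antagonist, at least 14.4-fold higher. Here and below "at least" counts log2 values below 4 as 4, because the table used here holds no detection calls and such signals lie in its lowest range. Fst, the activin-binding protein follistatin, was at least 13.9-fold higher, and Cemip, which takes part in hyaluronan breakdown, at least 8.77-fold higher. Serpine2, an inhibitor of thrombin and plasminogen activators, was 9.43-fold higher (log2 difference 3.24 ± 0.46 SE, limma adjusted p = 0.0102), and the chemokine receptor Cxcr1 at least 8.46-fold higher. The matrix proteoglycan Aspn (at least 5.33-fold higher) was lost without control 1, and Dmbt1, a mucosal scavenger protein (at least 8.6-fold higher), was lost without control 1, control 3, banding 2 or banding 3.

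Among the largest falls, Kcnk2, a mechanosensitive potassium channel, went from 5.85 ± 0.21 to 1.98 ± 0.11 (log2 mean ± SD, n = 3 each; adjusted p = 0.00046), which is at least 3.59-fold lower. Vtn, the adhesion protein vitronectin, was at least 11.2-fold lower, and Pdia5, a protein disulfide isomerase, at least 10-fold lower. Fam111a, a nuclear protease, was at least 32.1-fold lower, but its banding values varied with an SD of 1.74 and it was lost without control 3. Ly6al (at least 10.3-fold lower) was lost without control 1 or banding 3, Serpina1, the antiprotease alpha-1 antitrypsin (at least 5.7-fold lower), without control 2 or control 3, and Sema6a (8.06-fold lower) without control 1, control 3 or banding 3. Cped1 (at least 5.26-fold lower) passed only in the fit without control 2. Another 4 genes among the largest changes code for rat MHC molecules and moved both ways: RT1-CE10 was 11.8-fold and RT1-CE16 17.3-fold higher, whereas RT1-T24-3 was at least 32.6-fold and RT1-N2 at least 5.04-fold lower. RT1-CE16 passed only in the fit without control 1. Probe sets of such near-identical family members may cross-hybridise, so the assignment of these values to a single RT1 gene is uncertain.

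Of 15 measured macrophage genes, 9 rose and 0 fell, 12 and 0 when adjusted over the list alone, and all 15 lay higher in banding lungs with a median log2 difference of 1.41 (camera adjusted p = 1.41e-07, and adjusted p = 0.364 with an estimated correlation). Besides Trem2 and Mrc1, the lysosomal glycoprotein Gpnmb rose by 1.41 ± 0.20 (log2 ± SE) and the chitinase-like protein Chi3l1 by 0.96 ± 0.08. Of 13 genes of iron and heme handling, 5 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.35, but 0.15 without banding 1 and 0.89 with a stricter level filter; camera adjusted p = 0.00249, and adjusted p = 0.364 with an estimated correlation). They were Hmox1, the hemoglobin scavenger haptoglobin Hp (1.48 ± 0.19), the iron exporter Slc40a1 (2.15 ± 0.31), the siderophore-binding Lcn2 (1.30 ± 0.24) and the ferrireductase Steap4 (1.06 ± 0.21), the last named after its value was seen. Hmox1 was lost without control 1 or control 3, Lcn2 without any single control, and Steap4 without control 2, control 3, banding 2 or banding 3. With an array left out, 4 (without control 1 or control 3) to 9 (without banding 1) macrophage genes and 2 (without control 3) to 5 (without banding 1) genes of iron and heme handling rose.

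Endothelial genes were lower: 9 of 26 fell and 0 rose, with a median log2 difference of -0.62 (camera adjusted p = 1.48e-08, and adjusted p = 0.364 with an estimated correlation). Adjusted over the list alone, 17 fell and 2 rose. The receptor Calcrl, which binds adrenomedullin, fell by 2.02 ± 0.33 (log2 ± SE), Plvap, a protein of endothelial diaphragms, fell by 0.88 ± 0.13, and the peptide ligand Apln was 2.82-fold lower (limma adjusted p = 0.00454). Plvap was lost without control 1 and Calcrl without control 1 or banding 3. Of 8 lymphatic endothelial genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.068, and passed without control 1 or banding 2). The lymphoid chemokine Ccl21 rose by 2.41 ± 0.18, the scavenger receptor Stab1, which macrophages also express, by 1.28 ± 0.16, and Mmrn1 by 1.66 ± 0.23. Reln rose too, but its control mean was 2.98 and it was at least 1.16-fold higher, while the hyaluronan receptor Lyve1, named after its value was seen, fell by 1.72 ± 0.27. With an array left out, between 2 (without control 1) and 14 (without banding 1) endothelial genes fell. Reln was lost without control 1, control 3 or banding 3, and Lyve1 without control 1 or control 2.

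The 2 alveolar epithelial lists moved in opposite directions. Of 12 alveolar type I genes, 5 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.45, camera adjusted p = 3.48e-06, and adjusted p = 0.364 with an estimated correlation): Hopx fell by 0.50 ± 0.07, the water channel Aqp5 by 0.53 ± 0.10, Sema3e by 0.44 ± 0.10, the caveolar protein Cav1 by 0.46 ± 0.10 and Ager, named after its value was seen, by 0.35 ± 0.08. Of 17 alveolar type II genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.25, camera adjusted p = 0.0246, and adjusted p = 0.364 with an estimated correlation). Without banding 3 the type II list lost its camera call (adjusted p = 0.0539), and its median was 0.16 without control 3 or banding 3. The surfactant protein Sftpd rose by 0.56 ± 0.09, the phospholipid-remodelling enzyme Lpcat1 by 0.82 ± 0.14 and the lipid transporter Abca3 by 0.47 ± 0.09. With an array left out, 0 (without control 1 or banding 3) to 5 (without banding 1) type I genes fell and 1 (without any single control) to 5 (without banding 1) type II genes rose. None of these changed genes passed in each of the 6 fits. Among 13 genes of alveolar ion and fluid transport, the kinase Sgk1 rose by 1.13 ± 0.13, and Aqp5 and the epithelial sodium channel subunit Scnn1g (-1.18 ± 0.19) fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.068, and 0.039 without banding 2), with 0 falls without control 1, control 3 or banding 3. Scnn1g was lost without control 2 too. Of 14 airway epithelial genes 0 passed (0 adjusted over the list alone; camera adjusted p = 0.0513, and passed without control 1, banding 2 or banding 3). Their median lay 1.53 below the control mean on banding 1, against -0.03 on banding 2 and 0.11 on banding 3, and without banding 1, 1 of them rose and 2 fell.

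**Figure D2:**
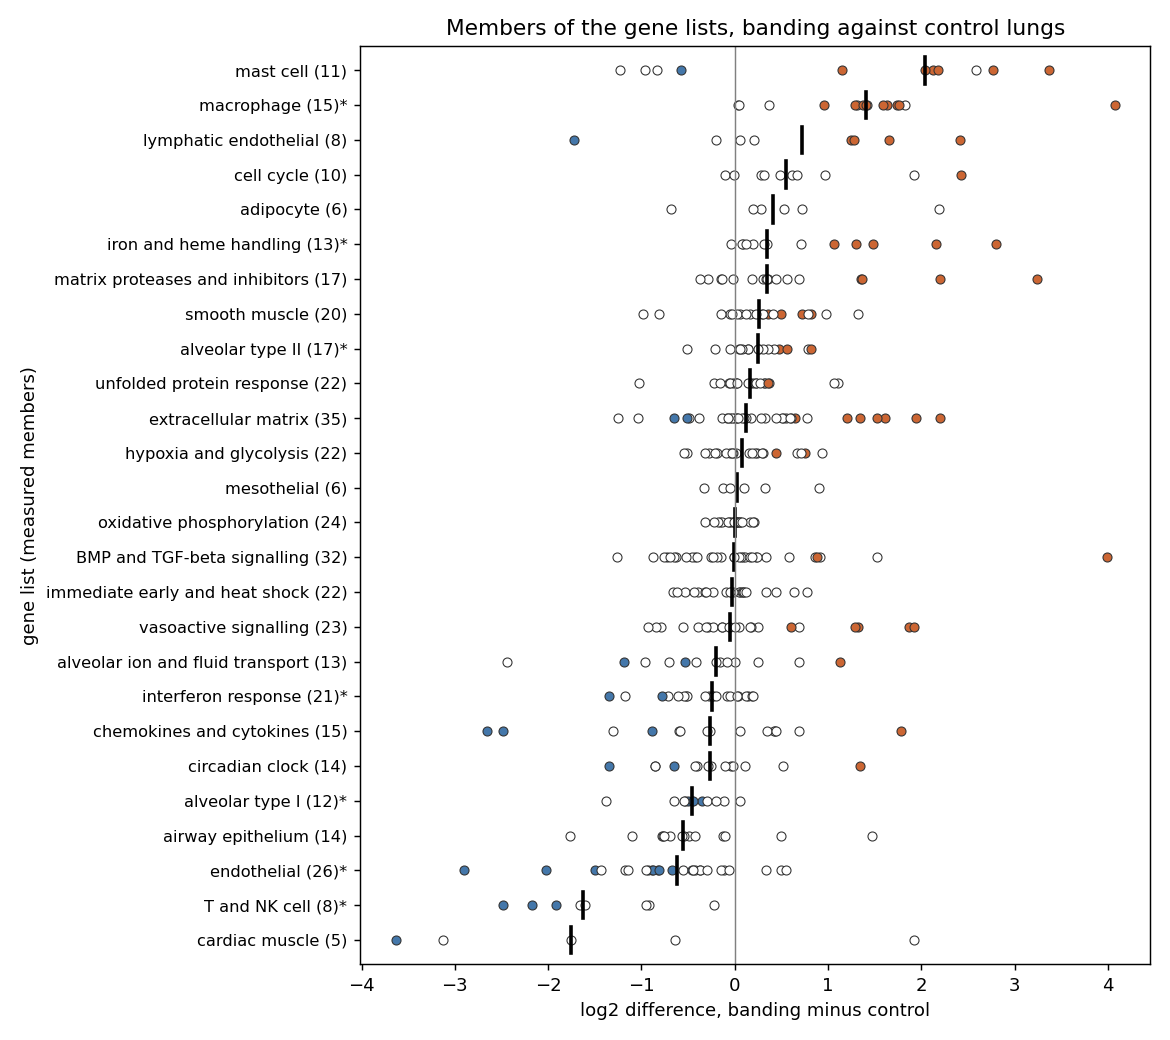
Log2 difference between banding and control lungs (horizontal axis) for every measured member of the 26 tested gene lists (vertical axis, number of measured members in brackets), ordered by the list median (black bar). Filled points passed limma's test, orange higher and blue lower in banding lungs, and an asterisk marks the 7 lists that passed camera with a preset correlation. The macrophage list has 9 filled points, all higher, and the endothelial list 9, all lower.

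Of 11 measured mast cell genes, 6 rose and 1 fell (7 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.068). Among fits that left out a single array, it passed camera only without control 2 or banding 3. Among the other settings the lowest camera adjusted p was 0.0092, and fry gave an adjusted p of 0.0317. The list median of 2.04 was 0.744 at its lowest among these settings. Mast cells are a subject of published work on this rat model, so this list may have been chosen on these samples and is not independent evidence of its direction. Cma1 was at least 5.43-fold higher. Mcpt1 rose by 2.18 ± 0.27, Mcpt1l1 by 3.37 ± 0.50, the tryptase Tpsb2 by 1.15 ± 0.26, and the carboxypeptidase Cpa3 by 2.12 ± 0.42 (log2 ± SE), while the exchanger Slc24a3 fell by 0.58 ± 0.12. The tryptase Tpsab1 was at least 2.61-fold higher. The protease Mcpt10 lay 2.58 ± 0.62 higher without passing (adjusted p = 0.0512). Other mast cell genes that did not pass had lower means in banding lungs: the log2 difference was -1.23 ± 0.40 for the stem cell factor receptor Kit, -0.96 ± 0.48 for the histamine-forming enzyme Hdc and -0.83 ± 0.43 for the transcription factor Gata2. With an array left out, 2 (without control 1 or control 3) to 7 (without control 2) of the 11 genes rose, and 0 fell except without banding 1, where Slc24a3 and Kit passed. Among these 6 fits, Tpsb2 and Mcpt10 passed only without control 2. Mcpt1l1 was lost without control 1 or control 3, Tpsab1 also without banding 2, and Cpa3 without these 3 or banding 3. Without banding 1, Kit lay at -1.63 (adjusted p = 0.0275), Hdc at -0.54 and Gata2 at -0.26, and without control 1, Hdc lay at -0.59. The Mcpt and tryptase genes have near-identical copies in the rat, so their separate values are uncertain.

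Genes of T and NK cells were lower: 3 of 8 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -1.63 over the 8 of 28 members past the level filter and -0.68 without that filter (camera adjusted p = 2.97e-05, and adjusted p = 0.364 with an estimated correlation). Ccl5 fell by 2.48 ± 0.24, while the cytotoxic granule genes Gzmb (at least 2.07-fold lower) and Prf1 (-1.91 ± 0.45) passed only in the fit without control 3. Gzma, another granule protease with a banding mean of 3.60, did not pass (limma adjusted p = 0.0529). Among fits that left out a single array it passed only without control 3, and it passed in 4 of 11 other settings. Between 1 gene, without any single array but control 3, and 4 genes, without control 3, of this list fell. Of 21 interferon response genes, 2 fell and 0 rose (5 and 0 adjusted over the list alone; median -0.24, camera adjusted p = 0.00134, and adjusted p = 0.364 with an estimated correlation): Isg15 by 0.78 ± 0.18 and Mx2 by 1.35 ± 0.31. Isg15 passed in 1 and Mx2 in 2 of the 6 fits that left out an array, and 0 genes of the list fell without control 1, control 2, control 3 or banding 3. A dimmer Mx2 probe set, with a control mean of 2.36, rose by at least 1.89, the only gene of 58 with several called probe sets in which they disagreed. Of 15 chemokines and cytokines, Il18 rose by 1.79 ± 0.23, and Ccl5, Il1a (-2.66 ± 0.60) and Kitlg, the ligand of Kit (-0.89 ± 0.13), fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.248), Il1a only in the fits without banding 1 or banding 2 among those that left out an array. Of 3 neutrophil genes, Lcn2 rose and the calgranulins S100a8 (-1.92 ± 0.41) and S100a9 (-1.58 ± 0.36) fell (1 and 2 adjusted over the list alone), and 0 passed without control 1 or control 3. S100a8 and S100a9 each passed in 1 of the 6 fits. Among 4 B and plasma cell genes, Xbp1 rose by 0.36 ± 0.08 (1 and 0 adjusted over the list alone), and it passed only in the fit without banding 1. Both of these lists were too short for the list test.

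Of 35 extracellular matrix genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.255, and 0.0412 without control 2). The elastic fibre genes Loxl1 and Ltbp2 rose by 1.21 ± 0.15 and 1.53 ± 0.20, the basement membrane collagen Col15a1 rose by 1.61 ± 0.31, and the proteoglycan Fmod fell by 0.65 ± 0.12, as did Sparc, named after its value was seen, by 0.51 ± 0.10. These counts were 2 and 0 without control 1, control 3 or banding 3, and 7 and 5 without banding 1. Col15a1 passed in 3, Fmod in 2 and Sparc in 1 of the 6 fits that left out an array. Among 17 matrix proteases and inhibitors, 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.056, and passed without control 2 or any single banding array): Serpine2, the cathepsins Ctss (1.35 ± 0.12) and Ctsk (2.20 ± 0.42), and the membrane-bound Mmp14 (1.36 ± 0.20). Without banding 1, 7 rose, and Ctsk was lost without control 1, control 2, control 3 or banding 2. Of 20 smooth muscle genes, 4 rose and 0 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.112, and 0.0236 without control 3). The myosin light chain Myl9 rose by 0.81 ± 0.10, but smooth muscle actin Acta2 (0.72 ± 0.17) passed in 0 of the 6 fits that left out an array, and Cald1 (0.35 ± 0.08) and Tpm1 (0.50 ± 0.10) passed only in the fit without banding 1. The mean of Tpm1's probe sets lay lower in banding lungs, at -1.05 (adjusted p = 0.295). Without control 1, banding 2 or banding 3, 1 smooth muscle gene rose.

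Of 23 genes of vasoactive signalling, 5 rose and 0 fell (5 and 2 adjusted over the list alone), although the list median was -0.05, its mean 0.16 and its camera direction downward (adjusted p = 0.944). The thromboxane synthase gene Tbxas1 rose by 1.87 ± 0.15. The cation channel Trpc6 was at least 2.15-fold higher. The vasoconstrictor endothelin Edn1 rose by 1.32 ± 0.26, the cyclooxygenase Ptgs1 by 0.60 ± 0.12 and Ramp3, named after its value was seen, by 1.29 ± 0.28. Edn1 and Ptgs1 passed only in the fit without banding 1, and Trpc6 was lost without control 1, control 2 or control 3. Ramp3 also passed only in the fit without banding 1. Without any single control, 1 gene of this list rose, and without banding 1, 5 rose and 1 fell. Of 32 genes of BMP and TGF-beta signalling, Fst and the receptor Tgfbr1 (0.88 ± 0.20) rose and Bmp4 (-0.73 ± 0.15) fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.404, with a median of -0.01 and a mean of 0.06). Without control 1, control 3 or banding 3, 1 gene of this list rose and 0 fell. Tgfbr1 and Bmp4 each passed in 2 of the 6 fits. The log2 difference of Bmpr2, the receptor mutated in heritable pulmonary arterial hypertension, was 0.07 ± 0.32 (adjusted p = 0.917; -0.14 to 0.42 with an array left out), which leaves changes in either direction open. The natriuretic peptide genes Nppa and Nppb lay under the level filter on all 6 arrays, between 1.39 and 2.33.

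Of 14 circadian clock genes, the repressor Bhlhe41 rose by 1.34 ± 0.14, and the output factors Hlf (-1.35 ± 0.21) and Dbp (-0.65 ± 0.13) fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.056, and passed without control 1, banding 2 or banding 3), with 0 falls without control 3 or banding 3. Hlf passed in 3 and Dbp in 2 of the 6 fits. Among 22 genes of hypoxia and glycolysis, Ndrg1 rose by 0.75 ± 0.10 and Ldha by 0.45 ± 0.09 (4 and 2 adjusted over the list alone; camera adjusted p = 0.565), the latter only in the fit without banding 1 among those that left out an array. Among 10 cell cycle genes, the mitotic kinase Aurkb rose by 2.43 ± 0.44 (2 and 0 adjusted over the list alone; camera adjusted p = 0.203, and 0.0433 without banding 2), and was lost without control 1, control 3, banding 2 or banding 3. The median of this list was 1.75 above the control mean on banding 1, and -0.16 and -0.10 on banding 2 and banding 3. The list has 33 members, and the level filter left out several that were high on banding 1 alone. Bub1, Nusap1 and Ube2c, named after their values were seen, lay at 6.28, 6.54 and 5.85 there and at 3.34 or less on the other arrays. Birc5 and Cenpa, also left out, lay at 2.45 or less on all arrays. Of 22 genes of the unfolded protein response, Xbp1 rose (0 adjusted over the list alone; camera adjusted p = 0.225), while 2 rose and 1 fell without banding 1 and 0 passed without any other single array. In oxidative phosphorylation (24 genes, camera adjusted p = 0.399, and 0.0302 without control 1, median 0.00115, mean -0.01, camera direction downward) and in immediate early and heat shock genes (22 genes, camera adjusted p = 0.401), 0 genes passed, also when adjusted over the list alone. Without banding 1, 3 immediate early and heat shock genes rose. Over all genes tested, 0 of 6 mesothelial genes (camera adjusted p = 0.944, median 0.02 with a downward camera direction) and 0 of 6 adipocyte genes (camera adjusted p = 0.14, and 0.0437 without control 2) passed, against 1 and 3 when adjusted over the list alone. Of 2 erythroid and 2 sex-linked genes 0 passed in either way.

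Transcripts of tissue other than lung parenchyma stood out on single arrays. Control 3 carried skeletal muscle and squamous epithelium transcripts at high level: Krt13 lay at 12.5, Krt4 at 12, Tnnc2 at 11.6 and Ckm at 11.2 on the log2 scale, against 3.2 or less on the other 5 arrays. These genes were chosen after their values were seen. Because most of them were low on 5 arrays, 2 genes of the skeletal muscle list passed the level filter and 0 changed. Without control 3, 1 of them, Acta1, rose. Of 5 measured cardiac muscle genes, 1 passed (1 and 1 adjusted over the list alone, camera adjusted p = 0.177, and 0.0253 without control 1). This was the cardiac myosin Myh6, which was at least 5.11-fold lower (limma adjusted p = 0.0478). Its control values were 4.93, 8.21 and 5.93, its banding values 3.88, 2.17 and 2.12, and it passed only in the fit without banding 1.

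**Figure D3:**
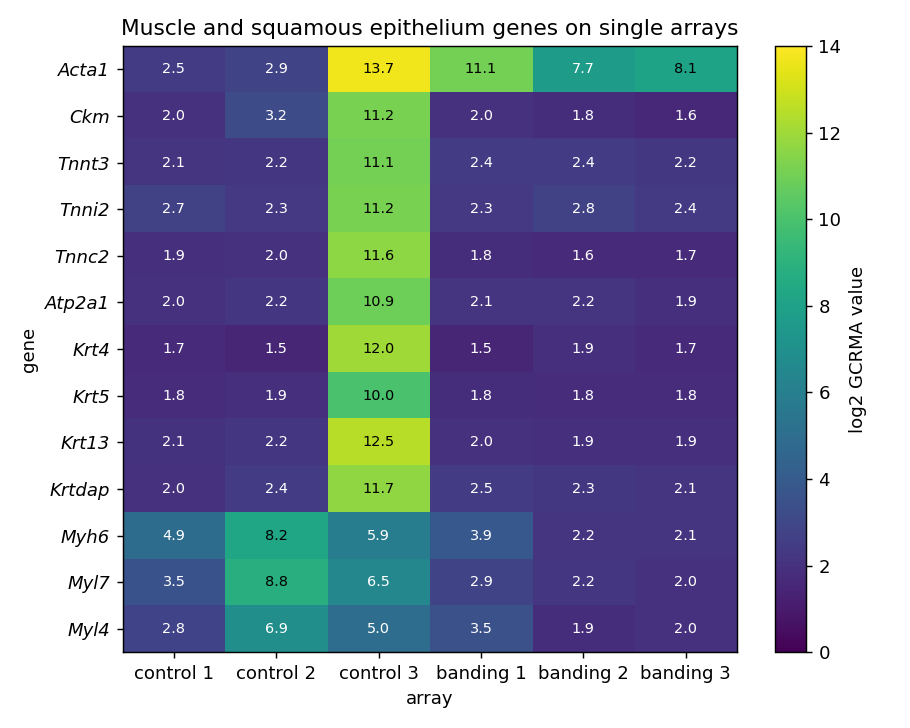
Log2 GCRMA values (colour and printed number) of skeletal muscle genes, squamous epithelium genes and cardiac muscle genes (rows) on the 6 arrays (columns). Krt4 reaches 12 on control 3 and stays below 2 on the other 5 arrays, while Myl7 is highest on control 2 at 8.78.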

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

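All tests in this part were chosen only after the values were seen. The level filter left out 127 probe sets that reached a log2 value of 6 or more on control 3, against 4 on control 1, 7 on control 2, 11 on banding 1, and 0 on banding 2 and banding 3. This signal lies outside the probe sets compared in the report.

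Skeletal muscle and keratin transcripts were among them. In control 3, 12 of 15 skeletal muscle genes (80%) and 12 of 13 genes of keratinised squamous epithelium lay at least 3 log2 units above both other controls, against 0.858% of all genes on the array; the squamous list was written after such genes were seen. A banding lung labelled control is argued against. Over genes called without control 3, that array lay at 0.0578 of the way from the other controls to the banding mean. The 95% bootstrap interval was 0.0207 to 0.0933. It resampled genes, so it does not measure the spread between arrays. A candidate explanation that remains is a piece of striated muscle with stratified epithelium carried along with the lung, since Krt13 at 12.5 and Tnnc2 at 11.6 are among its abundant transcripts; the design names no biological difference within the controls, so none was tested.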

How the results depend on the processing

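Alternatives were fixed before the data were examined, except leaving out control 3 and banding 1 together, averaging banding 2 and banding 3, raising values below 4 to 4, and counting changed list members and MHC probe sets without each array, which were chosen after seeing the data. The counts stayed within 1.5 times of the main ones (1034 probe sets, 501 at least 2-fold, 719 genes, 7 lists) under the stricter filters, quantile normalisation, median centring, no variance trend, a robust fit and the fit without control 3 and banding 1 together, and the 2-fold count was 458 with low values raised to 4. Without the level filter, 643 probe sets, 453 genes and 14 lists passed, and the cause was not tested. Array weights gave 2616 probe sets and 1742 genes; the cause was not tested. Averaging banding 2 and banding 3, which leaves fewer samples, gave 420 probe sets, 321 at least 2-fold, 310 genes and 11 lists, and camera with an estimated correlation gave 0 lists. Of the 7 lists, alveolar type II also lost its call with no variance trend, with banding 2 and banding 3 averaged and without banding 3 (adjusted p = 0.0539), and the T and NK list kept its call without the level filter with a median of -0.676. Leaving out each array in turn gave 344 to 1240 probe sets, 269 to 496 at least 2-fold, 249 to 881 genes and 8 to 13 lists, the lowest gene counts without control 1 and the highest without banding 1. Of the 719 genes, 243 were still called without control 1 and 652 without banding 1. The share of called probe sets that were higher, 61.7%, was 73.3% without control 1 and 53.6% without control 3 and banding 1. Same-numbered arrays did not deviate together (correlations of -0.107, -0.128 and -0.0113), which gives no sign that the numbers pair arrays. Deviations from a group mean balance each other within the group, so these correlations cannot exclude pairing. With the replicate number as a block 565 probe sets and 406 genes passed, and the mesothelial list kept its median of 0.0226 with an upward direction. Results that turned direction follow (for lists, camera's or fry's direction, which can differ from the median's sign); the cause was not tested, and except Mx2 and Tpm1 they did not pass in the main setting. Without the level filter the medians were 0.067 for the mesothelial list and 0.0539 for chemokines and cytokines. The vasoactive list changed its camera direction with no variance trend (median -0.0542), with array weights (-0.0674) and with the mean of a gene's probe sets (-0.0323). With fry, directions turned for the mesothelial (median 0.0226), BMP and TGF-beta (-0.00707) and vasoactive (-0.0542) lists. Leaving out single arrays gave medians of -0.0492 to 0.229 for extracellular matrix, -0.0731 to 0.12 for mesothelial, -0.0702 to 0.0347 for vasoactive, -0.155 to 0.906 for cell cycle, -0.258 to 0.0715 for immediate early and heat shock, and -0.0678 to 0.0771 for oxidative phosphorylation genes, and Bmpr2 values of -0.135 to 0.415. The medians of the airway list (-0.555 with all arrays, -0.842 without banding 3 to 0.0619 without banding 1) and of BMP and TGF-beta signalling (-0.138 to 0.0115) changed sign while camera's direction did not. Without control 3 and banding 1 together, extracellular matrix lay at -0.0816, cell cycle at -0.0079, immediate early genes at 0.102 and Myh1 at 0.00966. With banding 2 and banding 3 averaged, the mesothelial list lay at 0.0874 and Bmpr2 at -0.101. With the mean of a gene's probe sets, Tpm1 lay at -1.05 (limma adjusted p = 0.295) and Mx2 at 1.09 (limma adjusted p = 0.0152), because dimmer probe sets of both went the other way. Among the remaining single-gene values with all 6 arrays or an added setting, 1452 kept direction and call, 132 kept direction and lost the call and 56 gained it; with an array left out these numbers were 629, 189 and 13. For lists they were 313, 9 and 25, and 124, 1 and 22. Signal over background limits what genes with log2 values below 4 can show, since their differences depend on the background model.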

Other observations

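The tests in this part were chosen only after the results were seen, except the counts over other splits of the arrays. Complement and lysosomal genes, in lists written after the values of some members were seen, were mostly higher in banding lungs. Of 14 complement genes, 6 rose and 1 fell. C6 rose the most, Cfi by 2.51 ± 0.19 (log2 ± SE) and C5 by 2.06 ± 0.15. C1s rose by 0.95 ± 0.10, C1qc by 1.74 ± 0.34 and Cfp by 0.87 ± 0.19, whereas the complement inhibitor Cd55 fell by 0.90 ± 0.14. C1qc passed in 2 and Cfp in 0 of the 6 fits that left out an array, Cd55 was lost without control 1 or banding 3, and 4 complement genes rose without control 1, control 2, control 3 or banding 3. Of 30 lysosomal genes, 15 rose and 0 fell with a median of 0.56, among them the lipid-handling enzymes Ppt1 (1.03 ± 0.09) and Naaa (1.11 ± 0.09) and the hexosaminidase Hexa (0.74 ± 0.09), but 4 rose without control 1 or control 2, 5 without control 3, 7 without banding 3 and 10 without banding 2, and 17 without banding 1. With an estimated correlation, camera's unadjusted p was 0.0525 for the complement and 0.139 for the lysosomal list. Macrophages express many lysosomal genes, but a link of these rises to macrophages was not tested. The complement genes that passed in each of the 6 fits, C6, Cfi, C5 and C1s, are not in the macrophage list. Of its C1q genes, C1qa and C1qb lay higher without passing (limma adjusted p = 0.0648 and 0.0677).

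Skeletal muscle actin went its own way. Acta1 lay at 2.51 and 2.88 on control 1 and control 2 and at 13.7 on control 3, where other muscle genes were high too, but it also lay at 11.1, 7.67 and 8.14 on the banding arrays, where Ckm stayed at 2 or less and Tnnt3 at 2.41 or less. Its log2 difference of 2.63 ± 2.82 (SE) did not pass (limma adjusted p = 0.618), and without control 3 it was 6.28 (limma adjusted p = 0.0361), resting on control values below 4. The atrial genes Myl7 and Myl4 were highest on control 2, at 8.78 and 6.92, against 2.87 or less and 3.49 or less on the banding arrays. Banding 1 lay farther along the difference than the others. Over 881 genes called without it, its median was 1.26 of the distance from the controls to banding 2 and banding 3. The 95% bootstrap interval was 1.22 to 1.3, and it too resampled genes, not arrays.

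MHC probe sets, looked at because some stood among the largest changes, changed in both directions. Of 26 RT1 probe sets tested, 10 changed at least 2-fold (38.5%, against 3.53% of 13909 others), 5 higher and 5 lower, but 6 without control 3 (2 higher and 4 lower), and of 2 RT1-Bb probe sets the dimmer fell by at least 3.90 (limma adjusted p = 0.00158) while the brighter lay 1.27 ± 0.32 higher without passing (limma adjusted p = 0.0587). More antigen-presenting cells as the whole cause is argued against by the falls, 50% of those that changed and 4 to 6 probe sets in each fit that left out an array, although the rises of RT1-DMa (1.48 ± 0.26) and RT1-DMb (1.13 ± 0.18), both lost without control 1 or control 3, stay open to it. Cross-hybridisation between family members stays open, since 6 of 15 probe sets without a mark of sharing and 4 of 11 with it changed and near-identical genes can share probes in either. A candidate explanation that also stays open is a different MHC haplotype in the 2 groups of rats, as from different litters or stocks. The share that changed was seen before and cannot test it, the labels used here give no strain, and an effect of banding on these genes remains open. A difference in stock would not be limited to RT1 genes, so it stays open for the other changes reported here too.

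The mast cell proteases Cma1, Mcpt1 and Cpa3 rose, while Kit and Hdc had lower means without passing. Single arrays move this contrast: Kit passed without banding 1 (-1.63, limma adjusted p = 0.0275) and when adjusted over the list alone (adjusted p = 0.0206), Hdc lay at -0.537 without it and at -0.586 without control 1, and Cpa3 was lost without control 1, control 3, banding 2 or banding 3. Of the 8 list members with a control mean under 6, 6 rose, and of the 3 brighter ones 0, among them Gata2, which endothelial cells also express. That count rests on genes seen before, and the level filter shaped it. A member below 4 on all controls was counted only if its 3 banding values reached 4. The count therefore cannot separate more mast cells from more protease transcript per cell, an effect of banding that stays open as well. The list has 25 members, and those under the level filter were not tested. Among these, the non-protease gene Fcer1a lay at 1.45 to 2.68 in controls and 3.45 to 4.02 in banding lungs. Cd200r1 lay at 1.91 to 2.22 and 2.51 to 3.26. Mcpt4, Mcpt8, Mcpt9 and Hpgds overlapped between the groups. Ms4a2, Il1rl1 and Slc18a2, also not proteases, each had a probe set that lay higher in banding lungs without overlap, while their other probe sets overlapped. All of these values lie near or below 4. Proteases of related families read by each other's probe sets stay open too; Cpa3, of another family, is part of the pattern.

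The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only 1 split, the real one, gave 1034 changed probe sets, 501 changed at least 2-fold and 719 changed genes with limma; the highest count of any other split was 0 in each case. Of the gene lists, 7 shifted in the real split, and 9 of the 10 splits gave as many, the highest other count being 12. Every other split mixes control and banding arrays in both of its groups. It keeps part of any banding difference and adds the rest to the spread within groups. The counts of 0 are therefore no measure of what chance gives, and list calls there are not calls without a banding effect. The number of camera's list calls alone does not single out the real grouping. It cannot tell an effect of banding from other differences between arrays.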
